A study of Mus musculus with 18 samples.

How the data were processed

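RNA from 18 samples of mouse cells had been hybridised to whole-transcript mouse gene arrays, with 3 arrays in each of 6 groups. The groups were 2 unmixed lines, Comma-D and MMTV-neu, and the erbB2-negative and erbB2-positive fractions of their co-cultures at 1:50 and 1:1. Groups and replicate numbers were taken from the sample titles. The titles do not say which line makes up the 50 parts of a 1:50 co-culture, so no direction of the ratio is assumed.

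Per the submitters' processing notes, the deposited values are on the log2 scale and RMA, R 3.1.2 and limma were used. The level of summarisation, the handling of control probe sets and any filter are not given in the sources used here. The spread of the deposited values differed between groups, with a mean standard deviation per array of 1.98 in Comma-D, 1.53 in MMTV-neu, 1.99 and 1.85 in the erbB2-negative fractions of the 1:50 and 1:1 co-cultures, and 1.91 and 1.66 in their erbB2-positive fractions. The table holds 1 column per array, 0 columns of other samples and no missing values, and the most similar pair of arrays differed by up to 1.83 log2 units at a probe set. Arrays give no read depth, so only their number limits the precision that can be stated.

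Of 35556 probe sets, 23410 are in the probe annotation and 12146 are not. A single gene is given for 21789 of them and several genes for 1621, and these several-gene probe sets were left out of the gene-level tests. The reference gene table matched 21698 of the single-gene probe sets and changed 0 symbols. Each of the 19938 genes was represented by its probe set with the highest mean over all 18 arrays. Gene coordinates are not in the files used. No filter on low values was applied.

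Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of the 18 arrays with 12 residual degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The same fit gave the interaction, which is the difference between the 1:50 and 1:1 erbB2-positive fractions minus that between the erbB2-negative fractions. Lists of genes with at least 5 measured members, 25 in all, were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated for each list. Calls on list members are also counted as adjusted over the list alone.

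The position of an array between the unmixed lines is its projection on the mean MMTV-neu minus Comma-D difference over genes with an adjusted p under 0.05 and a difference of at least 2 log2 units, scaled so that the Comma-D mean is 0% and the MMTV-neu mean 100%. Positions were compared with two-sided exact permutation tests, which cannot give a p below 0.1 for 3 against 3 arrays. A gene was counted outside the range of the lines when a fraction lay above both, or below both, with an adjusted p under 0.05 in each comparison. These counts were set beside 20 simulated sets in which the fractions were linear-scale blends of the lines. The simulated noise was independent between arrays and taken from the spread of the unmixed arrays alone.

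The comparisons, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text may name the genes with the largest differences in either direction among called genes whose 3 and 3 arrays do not overlap and whose symbols are not provisional, 10 each way for a main comparison and 5 each way for the others and the interaction. It may also name the 4 members with the largest differences of each list described, the 6 genes above and 6 below farthest outside the range of the lines, and Erbb2, Erbb3, Egfr, Cdh1, Vim, Krt8 and Krt14. From that pool, members with a known function and a call that held when single arrays were left out were preferred, so the genes named are steadier than the pool. The genes drawn in plots were chosen from it after the values were seen. Stability counts were therefore taken over a wider set of 265 pairs of gene and comparison, unstable genes included. Of the 249 pairs outside the interaction, 232 were called, and in 231 of these the arrays of the compared groups did not overlap. The rule asked for this of the genes with the largest differences, so the count of 231 is no test of stability.

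Alternatives tried were leaving out the lowest 40% of genes, the mean of a gene's probe sets, every probe set on its own, trend and robust priors, array weights, centring on 11 reference genes, quantile normalization, a replicate block, a fit of the compared groups only, stricter thresholds and leaving out each array in turn. After the data were seen, a fit without the 3 MMTV-neu arrays and a replicate block in a fit of the 12 co-culture arrays were added, as were a paired exact test of axis positions within replicate numbers and draws of the interaction within those numbers. Whether equal replicate numbers pair samples was checked from correlations of residuals. By a bound on the lowest correlation within a number, 5 of 6 pairs of co-culture groups were taken as paired. The correlation within a number ranged from 0.0737 to 0.849 over the 6 pairs and the mean over other numbers from -0.311 to -0.0787. Residuals sum to 0 within a group, so those negative means are no separate evidence. A correlation between other numbers reached 0.586 for the 1:1 erbB2-negative and 1:50 erbB2-positive fractions, above their lowest within a number, 0.570. It reached 0.438 against 0.218 within the 1:1 co-culture, and 0.398 against 0.148 between the erbB2-positive fractions. In the 9 pairs with an unmixed line, 0 were paired.

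The procedure was tested on simulated data made with the pooled spread of each gene, in 10 runs of 19938 genes with changes placed between the 1:50 fractions. It found 94.6% of 2-fold and 100% of 4-fold changes with 12 false calls on average, called a shifted list in 10 of 10 runs and placed arrays on the axis with a largest error of 0.17 percentage points. That noise was independent between arrays and equal in all groups, unlike the real arrays, so detection and precision in the real comparisons may be lower. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Whether the 3 replicates are separate cultures or repeats of the same material is not stated, so p-values measure only the spread between these samples.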

Results

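Gene expression was measured in 6 groups of mouse cells with 3 arrays each. Comma-D is a mammary epithelial line from normal mouse tissue, and MMTV-neu cells come from mammary tumours driven by the neu (erbB2) oncogene. The labels call the first normal and erbB2-negative and the second cancer, erbB2-positive and phosphorylated-erbB2-positive. The lines were co-cultured at 1:50 or 1:1 in the Comma-D medium and then separated with an anti-erbB2 antibody and magnetic beads. The labels call the 1:50 erbB2-positive fraction redirected, with erbB2 present and its phosphorylated form absent, the 1:1 erbB2-positive fraction cancer, and both erbB2-negative fractions normal. MMTV-neu was grown in another medium, so line and medium cannot be separated in any comparison with it. Across genes, which are not independent replicates, Pearson's r between arrays was 0.994 to 0.995 within Comma-D, 0.9557 to 0.9753 within MMTV-neu and 0.730 to 0.759 between them.

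Erbb2 (probe set 10380896), the gene the cells were sorted on, did not separate the groups by their erbB2 labels. Its mean was 8.20 ± 0.11 log2 units (SD, n = 3) in Comma-D, 8.06 ± 0.14 in MMTV-neu, 8.27 ± 0.10 and 7.80 ± 0.07 in the 1:50 and 1:1 erbB2-negative fractions, and 8.22 ± 0.12 and 7.87 ± 0.04 in the erbB2-positive ones. Between MMTV-neu and Comma-D the difference was -0.14 (95% interval -0.35 to 0.0664, limma adjusted p = 0.184). Its sign depended on the scaling: it was 1.28 (adjusted p = 6.72e-07) with arrays centred on reference genes and 0.52 (adjusted p = 8e-04) after quantile normalization. In the 1:50 erbB2-positive fraction minus MMTV-neu it was 0.17 as deposited, -1.01 centred and -0.36 after quantile normalization. The reference genes themselves fell by 1.42 on average in MMTV-neu against Comma-D, so the centred values carry that fall. The transgene of MMTV-neu mice is the rat gene, and how well mouse probes read it was not tested.

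**Figure D1:**
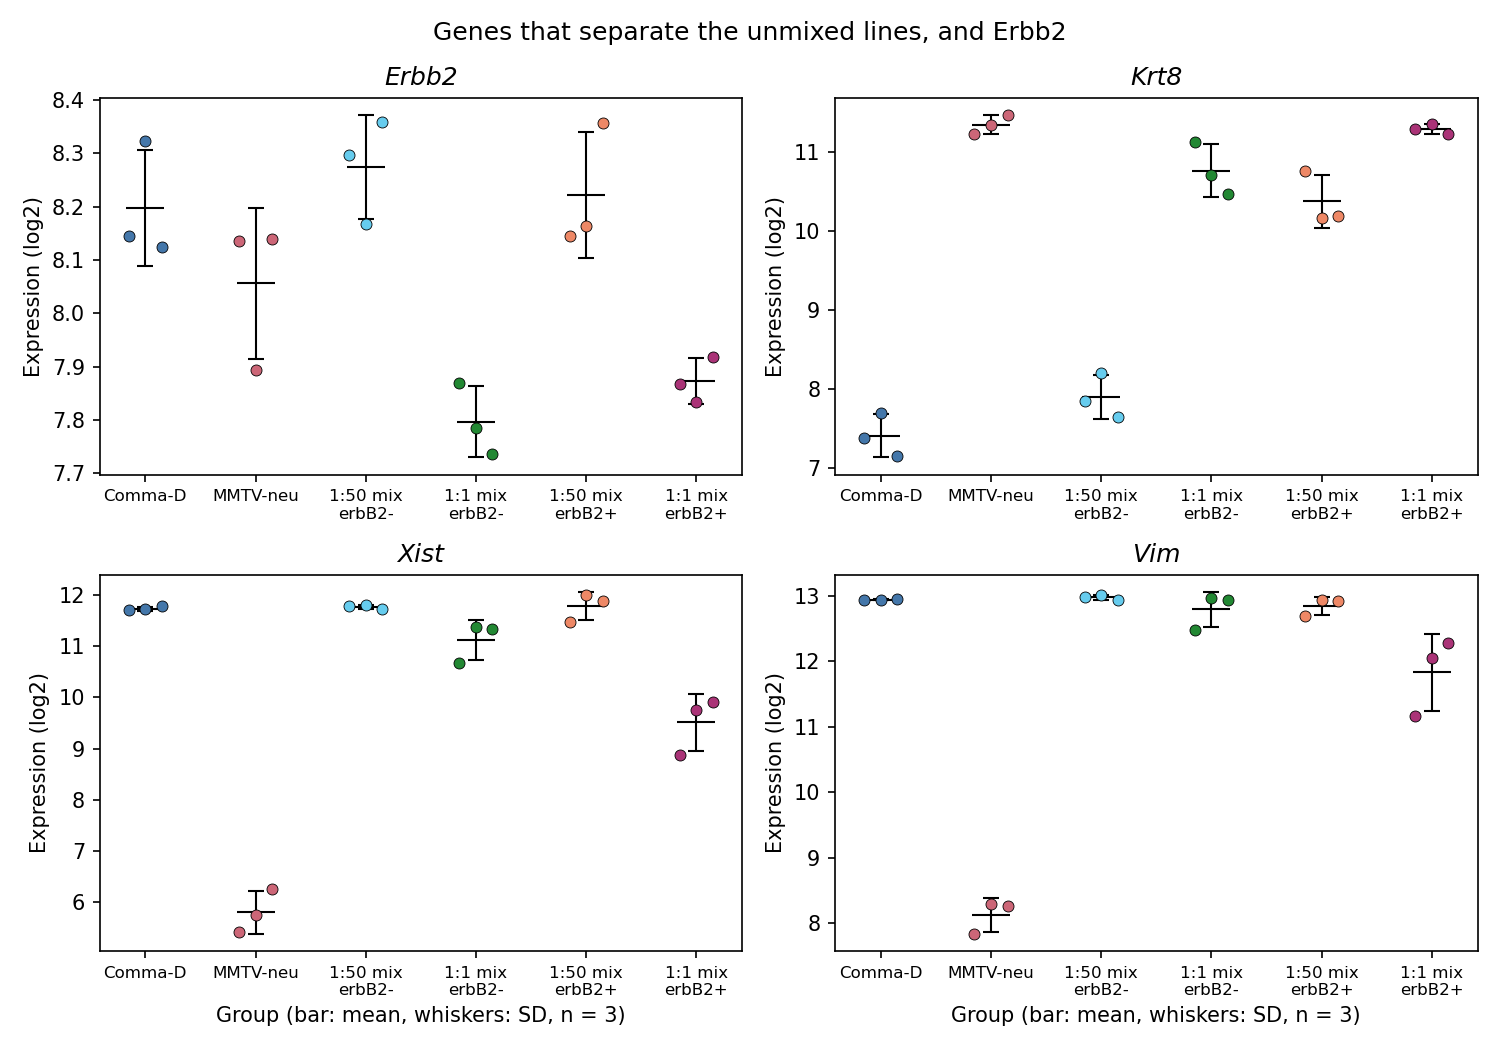
Log2 expression of Erbb2, Krt8, Xist and Vim on each array of the 6 groups, with axes that do not start at 0 (points: arrays; bar and whiskers: mean and SD, n = 3). Erbb2 spans 7.80 to 8.27 between group means, with a sign between the lines that turns under other scalings, while Krt8 lies at 7.41 in Comma-D and 11.34 in MMTV-neu, and Xist at 11.73 and 5.81.

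MMTV-neu was compared with Comma-D to give the difference between the unmixed lines on which the co-cultures are placed. The state of the MMTV-neu RNA could not be checked, and Actb, a cytoskeletal actin chosen after the values were seen, fell by 3.94 (SE 0.15), so falls in this line are not read as tumour biology alone. Eef1a1, likewise named outside the rule and at 13.34 in Comma-D beside 13.3 for Actb, fell by 0.946 (SE 0.0963). These 2 abundant transcripts thus fell unevenly. Krt8 (probe set 10432918), a keratin of luminal epithelium, rose by 3.93 (SE 0.19, 15.2-fold), Hoxc10, a homeobox gene, by 3.70 (SE 0.23) and Foxa1, a luminal transcription factor, by 2.73 (SE 0.21), n = 3 and 3. Of 28 luminal epithelial markers 14 rose and 10 fell, the same adjusted over the list alone, and the list was not called (median 0.3, mean -0.16, test downward, adjusted p = 0.5). At 2-fold or more 3800 genes were higher and 3707 lower, while at 2 log2 units or more 80 were higher and 1561 lower. The mitochondrially encoded COX2 fell by 7.38 (SE 0.17) and ND3 fell by 6.55 (SE 0.17). B2m, the light chain of class I antigens, fell by 6.31 (SE 0.20), the matrix gene Fn1 fell by 6.05 (SE 0.17), and Xist (probe set 10606178), which silences an X chromosome in female cells, fell by 5.93 (SE 0.25). COX2, ND3 and B2m lay at 5.05, 4.78 and 5.76 in MMTV-neu, under the medians of its arrays, where background compresses ratios, so their falls are lower bounds in size. The same holds for Xist at 5.81 and Scd1 at 6.15 in MMTV-neu. Hoxc10 lay at 5.04 in Comma-D, under the medians of its arrays, so its rise is a lower bound too. Vim, an intermediate filament of mesenchymal cells, fell by 4.80 (SE 0.21) and Krt14, a basal keratin, fell by 3.55 (SE 0.15).

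Basal and myoepithelial markers were lower in MMTV-neu, with 20 of 29 falling and 5 rising, the same counts when adjusted over the list alone (camera adjusted p = 7.05e-05, and adjusted p = 0.203 with an estimated correlation). Acta2, a smooth muscle actin, fell by 3.88 (SE 0.22) and Sparc by 5.10 (SE 0.14). Mesenchymal transition genes gave 19 falls and 4 rises among 27, again unchanged when adjusted over the list alone (adjusted p = 1.27e-06, and adjusted p = 0.15 with an estimated correlation). Of 30 genes of the unfolded protein response and amino acid stress, 28 fell and 1 rose, as they did adjusted over the list alone (adjusted p = 4.11e-09, and adjusted p = 0.183 with an estimated correlation). Slc3a2, an amino acid transporter chain, fell by 4.34 (SE 0.16) and Asns, asparagine synthetase, fell by 3.99 (SE 0.18). Cholesterol and fatty acid synthesis genes fell in 20 of 27 cases and rose in 4, with the same counts adjusted over the list alone (adjusted p = 7.83e-05, and adjusted p = 0.396 with an estimated correlation), and the desaturase Scd1 fell by 5.85 (SE 0.27). The immediate early and heat shock list, kept as a measure of sample handling, moved in the same direction, with 22 of 27 genes falling and 4 rising, also adjusted over the list alone (median -2.07, adjusted p = 1.27e-06, and adjusted p = 0.181 with an estimated correlation). Markers of 3 of the 4 cell types other than epithelium mostly rose, with equal counts adjusted over each list alone: 14 of 14 endothelial markers (adjusted p = 0.00279, and adjusted p = 0.362 with an estimated correlation), 18 of 20 macrophage and leukocyte markers (adjusted p = 0.0154, and adjusted p = 0.396 with an estimated correlation) and 10 of 11 adipocyte markers (adjusted p = 0.0735). Fibroblast markers did not, with 8 rising and 7 falling of 15, the same adjusted over the list alone, and the list was not called (median 0.298, mean -0.888, test downward, adjusted p = 0.288). In each of the 3 lists that rose only 2 genes exceeded the Comma-D median, and genes that low were higher in MMTV-neu in general.

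By limma, 17310 of 19938 genes were called, 11254 higher and 6056 lower in MMTV-neu, 7507 of them at 2-fold or more. With the lowest 40% of genes left out 41.7% of 9895 calls were higher. The libraries of 87.2% of genes did not overlap, against 10% by chance. The difference depended on the level of a gene: its median was 0.61 and 0.95 in the 4985 and 4984 genes lowest and next lowest in Comma-D, 0.0166 in the next 4984 and -1.37 in the highest 4985. A gradient by level ran through other comparisons too, and the tests of lists of abundant genes do not separate from it: the median of those 4985 highest genes was 1.05 for the 1:50 erbB2-positive fraction minus MMTV-neu, 0.923 between the erbB2-positive and 0.504 between the erbB2-negative fractions, -0.668 within the 1:1 co-culture and -0.503 for the 1:1 erbB2-negative fraction minus Comma-D. For the 1:50 erbB2-positive fraction minus Comma-D that median was -0.262. Centring on the reference genes raised the median of all genes by 1.42 and the share of higher calls from 65.0% to 89.9%. That 1.42 is the mean fall of the reference genes themselves, beside the median of -1.37 in the highest 4985 genes. Centring therefore sets every gene against genes that fell about as much as the abundant ones. Because it adds the same amount to every gene, it also turned Erbb3 from -1.11 to 0.31 and the median of 7 called lists, none of them named above, from negative to positive. Quantile normalization turned none of these 7 medians. No list of the 15 called was called with an estimated correlation.

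The 1:50 erbB2-positive fraction, called redirected by the labels, was compared with unmixed MMTV-neu. Comma-D RNA in the fraction and a change in MMTV-neu cells cannot be told apart in this comparison. Transcripts low in MMTV-neu were high in this fraction: COX2 rose by 7.60 (SE 0.17), Xist by 5.98 (SE 0.25), Fn1 by 5.85 (SE 0.17), Vim by 4.72 (SE 0.21) and Krt14 by 4.06 (SE 0.15), n = 3 and 3. The rises of COX2 and Xist and that of Scd1 start from MMTV-neu levels under the array medians and are lower bounds. Hoxc10 fell by 3.08 (SE 0.23), Tbx2, a T-box transcription factor, fell by 1.94 (SE 0.20), and Krt8 fell by 0.97 (SE 0.19). Hoxc10 ended at 5.664, under the array medians, so its fall is a lower bound. Basal and myoepithelial markers rose in 21 of 29 cases and fell in 5, also when adjusted over the list alone (adjusted p = 1.53e-07, and adjusted p = 0.137 with an estimated correlation), and Krt5 rose by 3.43 (SE 0.26). Cholesterol and fatty acid synthesis genes rose in 20 of 27 cases and fell in 4, with equal counts adjusted over the list alone (adjusted p = 5.64e-07, and adjusted p = 0.256 with an estimated correlation), Scd1 by 5.70 (SE 0.27). The handling list of immediate early and heat shock genes moved the same way, with 18 of 27 rising and 4 falling, unchanged adjusted over the list alone (adjusted p = 2.1e-05, and adjusted p = 0.172 with an estimated correlation), and its median turned from 0.828 to -0.352 with centring. Markers of 3 other cell types mostly fell, with the same counts adjusted over each list alone: 13 of 14 endothelial (adjusted p = 0.00529, and adjusted p = 0.363 with an estimated correlation), 18 of 20 macrophage and leukocyte, with 2 rising (adjusted p = 0.0192, and adjusted p = 0.365 with an estimated correlation) and 11 of 11 adipocyte markers (adjusted p = 0.0254, and adjusted p = 0.365 with an estimated correlation). Fibroblast markers were not called, with 6 rising and 9 falling of 15, the same adjusted over the list alone (median -0.385, mean 0.511, test upward, adjusted p = 0.502).

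In all, 16621 genes were called, 5136 higher and 11485 lower. The balance turned among strong signals: at 2-fold or more 2870 were higher and 2161 lower, and with the lowest 40% of genes left out 54.5% of calls were higher. The compared arrays of 81.4% of genes did not overlap, against 10% by chance. Of 25 lists 16 were called, and 0 with an estimated correlation. The median of all genes moved by -1.18 with centring, and the share of higher calls from 30.9% to 9.16%.

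Against the normal line grown in the same medium, the 1:50 erbB2-positive fraction differed at far fewer genes. Krt8 rose by 2.96 (SE 0.19, 7.77-fold, adjusted p = 5.05e-08), the calcium sensor Vsnl1 by 2.19 (SE 0.38), the small nucleolar RNA Snora20 by 2.10 (SE 0.23), the basal keratin Krt5 by 1.37 (SE 0.26) and Igfbp3, which binds insulin-like growth factors, by 1.36 (SE 0.17), n = 3 and 3. Dcn, the matrix proteoglycan decorin, fell by 3.42 (SE 0.16), Itih2 fell by 3.101 (SE 0.15), the growth factor Igf2 fell by 3.06 (SE 0.14), Angpt1 fell by 2.58 (SE 0.15) and Pdgfra, a receptor of mesenchymal cells, fell by 2.32 (SE 0.35). Xist (0.06, SE 0.25, adjusted p = 0.921) and Erbb2 (0.02, SE 0.10, adjusted p = 0.912) were not called. Dcn ended at 5.063, Itih2 at 5.976 and Angpt1 at 5.867, under the array medians, so these falls are lower bounds. The same holds for Dcn in the erbB2-negative fractions. Endothelial markers were called upward with 0 of 14 members called, as adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.611 with an estimated correlation).

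Of 28 hypoxia and glycolysis genes 11 fell and 0 rose, and adjusted over the list alone 16 fell and 1 rose (camera adjusted p = 1.22e-08). This list was also called with an estimated correlation (adjusted p = 0.00683). Its median was -0.42, or -0.177 with centring, beside -0.262 as deposited for the 4985 genes highest in Comma-D. Ak4 fell by 1.20 (SE 0.18) and Eno2 fell by 1.16 (SE 0.14), the latter with adjusted p = 0.0528 when arrays were centred on the reference genes. Immediate early and heat shock genes fell in 10 of 27 cases, 14 adjusted over the list alone (median -0.576, or -0.333 with centring, adjusted p = 1.22e-08, and adjusted p = 0.177 with an estimated correlation). Among them Fosb fell by 2.27 (SE 0.29), Fos by 1.72 and Socs3 by 1.55, where Fosb and Fos encode transcription factors and Socs3 a feedback inhibitor of cytokine signalling. Of 29 ERBB receptors, ligands and feedback genes 9 fell, 10 adjusted over the list alone (adjusted p = 2.16e-04, and adjusted p = 0.162 with an estimated correlation): Dusp6, a phosphatase that limits ERK, fell by 1.88 (SE 0.19), Errfi1, an inhibitor of ERBB receptors, fell by 1.34 (SE 0.13), and the ligand Hbegf fell by 1.29 (SE 0.13). The median of that list turned from -0.0785 to 0.164 with centring and was -0.0511 after quantile normalization. Basal and myoepithelial markers rose in 4 of 29 cases and fell in 1, against 7 and 1 adjusted over the list alone (adjusted p = 0.00416, and adjusted p = 0.611 with an estimated correlation). Of 23 milk protein and lactation genes 4 fell, 5 adjusted over the list alone, and the list was not called (adjusted p = 0.31), although the casein gene Csn3 fell by 2.20 (SE 0.14) and the lactoferrin gene Ltf by 1.68 (SE 0.22).

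The test called 1139 genes, 233 higher and 906 lower. Without Comma-D replicate 1, 2 or 3 it called 512, 596 or 441, and without replicate 1 or 3 of the fraction 500 or 597. Centring on the reference genes moved the median of all genes by 0.243 and left 220 calls, with 42.3% higher instead of 20.5%. Quantile normalization left 406, a fit of the compared arrays alone gave 2123, and a replicate block gave 1875.

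The erbB2-positive fractions of the 1:50 and 1:1 co-cultures, which the labels call redirected and cancer, differ by ratio in a shared medium. Krt14 was higher in the 1:50 fraction by 1.80 (SE 0.15), the basal integrin subunits Itga6 and Itgb4 by 2.29 (SE 0.25) and 1.71 (SE 0.17), Xist by 2.27 (SE 0.25), the adhesion gene Epcam by 2.20 (SE 0.39) and Cdh1, E-cadherin, by 1.87 (SE 0.26), n = 3 and 3. Lower in it were Hoxc10, which fell by 2.26 (SE 0.23), the histone gene H4c3, which fell by 1.76 (SE 0.18), and Krt8, which fell by 0.92 (SE 0.19). The fall of Hoxc10, which ended at 5.664, under the array medians, is a lower bound. Basal and myoepithelial markers rose in 20 of 29 cases and fell in 3, with those counts also adjusted over the list alone (adjusted p = 2.38e-05, and adjusted p = 0.236 with an estimated correlation). Unfolded protein response and amino acid stress genes rose in 25 of 30 cases and fell in 1, the same adjusted over the list alone (adjusted p = 2.33e-07, and adjusted p = 0.236 with an estimated correlation), including Dnajb9 by 1.89 (SE 0.22) and Asns by 1.69 (SE 0.18). Among 27 cholesterol and fatty acid synthesis genes 20 rose and 3 fell, unchanged adjusted over the list alone (adjusted p = 2.38e-05, and adjusted p = 0.358 with an estimated correlation), with Fasn, fatty acid synthase, up by 2.27 (SE 0.27). Interferon-stimulated genes rose in 17 of 28 cases and fell in 6, again unchanged adjusted over the list alone (adjusted p = 5.3e-04, and adjusted p = 0.184 with an estimated correlation). The median of the interferon list turned from 0.526 to -0.255 with centring and was 0.564 after quantile normalization. The handling list of immediate early and heat shock genes rose alongside, in 14 of 27 cases with 2 falling, also adjusted over the list alone (adjusted p = 5.3e-04, and adjusted p = 0.35 with an estimated correlation), and its median turned from 0.655 to -0.127 with centring. Endothelial markers fell in 12 of 14 cases and adipocyte markers in 10 of 11, the same adjusted over each list alone (adjusted p = 0.0133 and 0.0173, and adjusted p = 0.375 and 0.358 with an estimated correlation). Of 20 macrophage and leukocyte markers 16 fell and 2 rose, against 17 and 2 adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.395 with an estimated correlation). Fibroblast markers were not called, with 6 rising and 7 falling of 15, unchanged adjusted over the list alone (median -0.159, mean 0.24, test upward, adjusted p = 0.757).

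The number of genes called was 14240, 5466 higher and 8774 lower. At 2-fold or more 2601 were higher and 526 lower, and with the lowest 40% of genes left out 60.6% of calls were higher, so the balance turned. The arrays of 78.7% of genes did not overlap, against 10% by chance. Centring moved the median of all genes by -0.782, the share of higher calls from 38.4% to 11.9%, the difference of Erbb2 from 0.35 (adjusted p = 0.00496) to -0.43 (adjusted p = 0.0375), and that of Vim from 1.02 (adjusted p = 5.44e-04) to 0.23 (adjusted p = 0.244).

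The 1:1 erbB2-positive fraction kept the label cancer and was compared with unmixed MMTV-neu. COX2 rose by 7.18 (SE 0.17), ND3 by 4.79 (SE 0.17), Fn1 by 4.48 (SE 0.17), Xist by 3.71 (SE 0.25), Vim by 3.70 (SE 0.21) and Acta2 by 2.96 (SE 0.22), while Nr2f1, a nuclear receptor, fell by 1.21 (SE 0.18), n = 3 and 3. The rises of COX2, ND3 and Xist are again lower bounds. Krt8 was not called (-0.05, SE 0.19, adjusted p = 0.868). Collagens and matrix genes rose in 13 of 33 cases and fell in 0, against 14 and 1 adjusted over the list alone (adjusted p = 5.29e-13, and adjusted p = 0.0589 with an estimated correlation). Of 29 basal and myoepithelial markers 10 rose and 1 fell, against 12 and 2 adjusted over the list alone (adjusted p = 5.45e-12, and adjusted p = 0.0589 with an estimated correlation). The set test was upward for the stem and progenitor list, of which 4 of 24 rose and 1 fell, against 5 and 2 adjusted over the list alone, although its median was -0.0399, or 0.0379 after quantile normalization (adjusted p = 0.0262, and adjusted p = 0.096 with an estimated correlation). The handling list of immediate early and heat shock genes was also called upward, with 8 of 27 rising and 1 falling, as adjusted over the list alone (adjusted p = 4.16e-06, and adjusted p = 0.158 with an estimated correlation), and its median turned from 0.23 to -0.168 with centring. Endothelial markers fell in 4 of 14 cases, 9 adjusted over the list alone (adjusted p = 0.00598, and adjusted p = 0.391 with an estimated correlation), and macrophage and leukocyte markers in 6 of 20, 13 adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.448 with an estimated correlation). Neither fibroblast (3 of 15 rising, 1 falling, 2 falling adjusted over the list alone, median -0.0723, mean 0.271, test upward, adjusted p = 0.088) nor adipocyte markers (2 of 11 falling, also adjusted over the list alone, adjusted p = 0.363) were called.

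For this comparison 3658 genes were called, 840 higher and 2818 lower. The balance turned at 2-fold or more, with 389 higher and 2 lower, and with the lowest 40% of genes left out, with 63.1% higher. Without replicate 2 or 3 of the fraction 1814 or 1362 were called. Centring moved the median of all genes by -0.398 and gave 12864 calls with 4.03% higher instead of 23%. Quantile normalization gave 36.3% higher, and a fit of the compared arrays alone gave 793 calls with 71% higher. The positive medians of the collagen and basal lists (0.0811 and 0.266) became negative with centring (-0.316 and -0.132) and stayed positive after quantile normalization (0.0402 and 0.338).

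The erbB2-negative fraction of the 1:50 co-culture was compared with Comma-D that had not been mixed. Vsnl1 rose by 2.27 (SE 0.38), C1qtnf3 by 1.54 (SE 0.26) and Krt5 by 1.53 (SE 0.26), n = 3 and 3. Dcn fell by 3.40 (SE 0.16), Igf2 fell by 3.13 (SE 0.14), Itih2 fell by 2.65 (SE 0.15), the casein gene Csn3 fell by 2.06 (SE 0.14) and Pdgfra fell by 1.93 (SE 0.35). Krt8 was 0.49 higher without being called (SE 0.19, adjusted p = 0.366). Fibroblast markers were called downward, with 2 of 15 falling and 1 rising, the same adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.299 with an estimated correlation).

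Immediate early and heat shock genes fell in 8 of 27 cases, while adjusted over the list alone 10 fell and 1 rose (adjusted p = 4.34e-14, and adjusted p = 0.0326 with an estimated correlation), Fosb by 2.37 (SE 0.29) and Fos by 1.59 (SE 0.16). Of 28 hypoxia and glycolysis genes 6 fell, 9 adjusted over the list alone (adjusted p = 2e-09, and adjusted p = 0.00527 with an estimated correlation), with Eno2, neuronal enolase, falling by 1.11 (SE 0.14) and Hk2, a hexokinase, by 0.84 (SE 0.13). Among 29 ERBB receptors, ligands and feedback genes 7 fell, and adjusted over the list alone 10 fell and 2 rose (adjusted p = 5.56e-06, and adjusted p = 0.0326 with an estimated correlation), with Dusp6 down by 1.45 on the log2 scale and Errfi1 by 1.09. Interferon-stimulated genes rose in 4 of 28 cases, 11 adjusted over the list alone (adjusted p = 2e-09, and adjusted p = 0.0212 with an estimated correlation). The call on Usp18 (0.97, SE 0.24, adjusted p = 0.0444), an interferon-induced protease gene, was lost without any of the 6 arrays. Basal and myoepithelial markers rose in 4 of 29 cases and fell in 1, against 10 and 2 adjusted over the list alone (adjusted p = 4.66e-07, and adjusted p = 0.196 with an estimated correlation).

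Calls numbered 334, 118 higher and 216 lower. They numbered 159, 173 or 154 without Comma-D replicate 1, 2 or 3 and 146 or 201 without replicate 2 or 3 of the fraction, 128 with centring, 188 after quantile normalization and 1045, with 55.5% higher instead of 35.3%, in a fit of the compared arrays alone.

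In the 1:1 co-culture the erbB2-negative fraction moved further from Comma-D. Krt8 rose by 3.35 (SE 0.19), C1qtnf3 by 2.49 (SE 0.26) and Krt5 by 1.23 (SE 0.26), n = 3 and 3. Cyp2f2, a cytochrome P450, fell by 3.45 (SE 0.21), Dcn fell by 3.24 (SE 0.16), the cytokine Il6 fell by 3.19 (SE 0.30), Kit, a receptor of luminal progenitors, fell by 2.57 (SE 0.25) and the epithelial transcription factor Ehf fell by 2.49 (SE 0.22). Immediate early and heat shock genes fell in 19 of 27 cases, also when adjusted over the list alone (adjusted p = 2.66e-06, and adjusted p = 0.25 with an estimated correlation). Of 29 ERBB receptors, ligands and feedback genes 16 fell and 1 rose, against 16 and 2 adjusted over the list alone (adjusted p = 7.39e-04, and adjusted p = 0.237 with an estimated correlation). Among 29 epithelial junction genes 11 fell and 3 rose, against 12 and 3 adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.25 with an estimated correlation), Epcam falling by 1.87 (SE 0.39) and Cldn1, a tight junction claudin, by 1.69 (SE 0.19). Endothelial markers were called upward, with 3 of 14 rising, 2 adjusted over the list alone (adjusted p = 0.00589, and adjusted p = 0.44 with an estimated correlation). Of 11 adipocyte and 20 macrophage and leukocyte markers 5 each rose and 1 each fell, also adjusted over each list alone, without a call (adjusted p = 0.163 and 0.0511).

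Of 7121 genes called, 2963 were higher and 4158 lower, and the count was 4621 or 3892 without Comma-D replicate 1 or 3 and 2885 without replicate 1 of the fraction. Simulated blends of the lines, which need no change in the cells, gave 6622 to 6844 calls for this comparison. A single MMTV-neu share per array accounted for 49.5% to 76.3% of the squared difference from Comma-D over axis genes, and for 31% to 75.2% over all genes. Centring moved the median of all genes by 0.387, the share of higher calls from 41.6% to 89.5% and the median of the junction list from -0.208 to 0.179, against -0.129 after quantile normalization. Quantile normalization gave 3108 calls with 57.3% higher and a fit of the compared arrays alone 4231.

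Between the erbB2-negative fractions, Krt8 was lower at 1:50 than at 1:1, where it fell by 2.86 (SE 0.19), while Ehf, Ceacam1, Cldn1 and Cdh1 were higher by 2.15 (SE 0.22), 1.98 (SE 0.19), 1.89 (SE 0.19) and 1.47 (SE 0.26), n = 3 and 3. Interferon-stimulated genes rose in 18 of 28 cases, 19 adjusted over the list alone (adjusted p = 5.85e-05, and adjusted p = 0.145 with an estimated correlation). Epithelial junction genes rose in 14 of 29 cases and fell in 1, against 17 and 2 adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.145 with an estimated correlation). Endothelial, macrophage and leukocyte, and adipocyte markers were called downward (adjusted p = 0.0182, 0.0193 and 0.0182, and adjusted p = 0.492 each with an estimated correlation), with 0 of 14, 4 of 20 and 3 of 11 falling and 1 macrophage marker rising, the same adjusted over each list alone. The count of 6041 called genes, 4273 higher and 1768 lower, was fragile. It was 1065 without replicate 1 of the 1:1 fraction and 3178, 2845 or 2624 without replicate 1, 2 or 3 of the 1:50 fraction, and with the 6 compared arrays alone it was 2, Krt8 among them, which ended the calls on Ehf, Ceacam1, Cldn1 and Cdh1. Centring moved the median of all genes by -0.395 and the share of higher calls from 70.7% to 5.59%. Quantile normalization gave 901 calls with 48.5% higher, and a replicate block in a fit of the 12 co-culture arrays gave 9438.

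Within the 1:50 co-culture, the erbB2-positive and erbB2-negative fractions differed at 2 genes, both higher in the erbB2-positive fraction: Krt8 by 2.47 (SE 0.19, 5.53-fold, adjusted p = 7.09e-06) and Snora20 (probe set 10441813) by 2.45 (SE 0.23, 5.46-fold, adjusted p = 5.4e-05), n = 3 and 3. Snora20 lay at 5.668 in the erbB2-negative fraction, under the array medians, so its difference is a lower bound. Xist, Vim and Krt14 had means of 11.79, 12.85 and 11.49 in the erbB2-positive and 11.77, 12.97 and 11.61 in the erbB2-negative fraction. Interferon-stimulated genes were called as a list, lower in the erbB2-positive fraction, with 0 of 28 members called over all genes and 8 falling when adjusted over the list alone (adjusted p = 7.7e-06, and adjusted p = 0.182 with an estimated correlation). Unfolded protein response and amino acid stress genes were also lower as a list with 0 of 30 members called, as adjusted over the list alone (adjusted p = 2.08e-05, and adjusted p = 0.492 with an estimated correlation). Their median of -0.315 was close to the -0.263 of all genes in the group of 4985 highest in Comma-D. Macrophage and leukocyte, endothelial and adipocyte markers were called upward (adjusted p = 0.0221, 0.0451 and 0.0355, and adjusted p = 0.492, 0.587 and 0.492 with an estimated correlation), with 0 members called in each, also adjusted over each list alone. At an unadjusted p under 0.05 the limma fit gave 2675 genes, and with the 6 compared arrays alone it called 0 (adjusted p = 0.136 for Krt8 and 0.183 for Snora20), while 27 were called when each probe set was tested on its own. The arrays of 29.1% of genes did not overlap, against 10% by chance, so the few calls do not show that the fractions are alike. The median of all genes moved by 0.251 with centring.

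Within the 1:1 co-culture the fractions were far apart. Hoxc10 and Hoxc6 were higher in the erbB2-positive fraction by 1.36 (SE 0.23) and 1.02 (SE 0.18), and Gstp1, a glutathione transferase, fell by 2.24 (SE 0.21), Xist fell by 1.61 (SE 0.25) and Krt14 fell by 1.29 (SE 0.15), n = 3 and 3. Unfolded protein response and amino acid stress genes fell in 22 of 30 cases and rose in 1, against 23 and 1 adjusted over the list alone (adjusted p = 1.11e-08, and adjusted p = 0.217 with an estimated correlation). Mesenchymal transition genes fell in 17 of 27 cases and rose in 1, as they did adjusted over the list alone (adjusted p = 7.98e-07, and adjusted p = 0.139 with an estimated correlation). The handling list of immediate early and heat shock genes fell with them, in 13 of 27 cases with 4 rising, against 14 and 4 adjusted over the list alone (adjusted p = 2.43e-04, and adjusted p = 0.28 with an estimated correlation), and its median turned from -0.564 to 0.0736 with centring. Macrophage and leukocyte markers rose in 11 of 20 cases and endothelial markers in 10 of 14, with 1 falling in each, against 12 and 11 rising adjusted over each list alone (adjusted p = 0.0214 each, and adjusted p = 0.439 each with an estimated correlation). Adipocyte markers rose in 7 of 11 cases, the same adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.439 with an estimated correlation), while 5 of 15 fibroblast markers rose and 5 fell, as adjusted over the list alone, without a call (median 0.134, mean -0.263, test downward, adjusted p = 0.504). The calls numbered 11195, 7017 higher and 4178 lower. The balance turned at 2-fold or more, with 9 higher and 1617 lower, and with the lowest 40% of genes left out, with 43.1% higher. There were 6737 calls without replicate 3 of the erbB2-negative fraction and 6904 with the compared arrays alone. With centring the median of all genes moved by 0.637 and the share of higher calls from 62.7% to 91.1%.

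The ratio effect was also compared between the sorted fractions. For Krt8 the 1:50 minus 1:1 difference was -0.92 in the erbB2-positive and -2.86 in the erbB2-negative fraction, an interaction of 1.94 (SE 0.27, adjusted p = 0.00286). The stress-induced phosphatase gene Dusp1 differed by 2.04 and 0.45 (interaction 1.59, SE 0.16) and the small nucleolar RNA Snord82 by 2.42 and 0.27 (interaction 2.15, SE 0.18). Mesenchymal transition genes had an upward interaction in 7 of 27 cases, 14 adjusted over the list alone (adjusted p = 8.1e-09, and adjusted p = 0.0737 with an estimated correlation). The handling list of immediate early and heat shock genes was called upward too, with 1 of 27 members called, as adjusted over the list alone (median 0.438, adjusted p = 6.26e-06, and adjusted p = 0.185 with an estimated correlation). In all 548 genes were called, 488 positive and 60 negative. The count was 2 with centring, which moved the median of all genes by -0.386, 67 with the co-culture arrays alone, 946 after quantile normalization with 70.9% positive instead of 89.1%, and 1288 with a replicate block. It was 351, 217 or 128 without replicate 1, 2 or 3 of the 1:50 erbB2-negative fraction, 5303, 115 or 173 without those of the 1:1 erbB2-negative fraction, 1498, 125 or 246 without those of the 1:50 erbB2-positive fraction and 164, 322 or 917 without those of the 1:1 erbB2-positive fraction. The balance turned without replicate 1 of the 1:1 erbB2-negative fraction, where 2461 of the 5303 calls were positive and 2842 negative, and a replicate block in a fit of the 12 co-culture arrays gave 60.8% positive.

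The position of each fraction between the lines was read from 1641 genes, 80 higher and 1561 lower in MMTV-neu. Positions thus mostly measure how much of the signal low in MMTV-neu a fraction holds. Falls in that line are not read as tumour biology alone, so the axis is not a scale from normal to tumour. The 1:50 erbB2-negative fraction lay at 3.27% ± 0.977 (SD, n = 3), the 1:50 erbB2-positive fraction at 14.3% ± 8.04, the 1:1 erbB2-negative fraction at 26.0% ± 14.0 and the 1:1 erbB2-positive fraction at 69.4% ± 10.0 of the way from Comma-D to MMTV-neu. The first of these positions was lower with centring and as a median over axis genes, as given further on. On the linear scale the 1:50 erbB2-positive fraction lay at 16.94% ± 10.1. On that scale Krt8 in it lay 48.7% ± 13.7 of the way to MMTV-neu, Foxa1 17.2% ± 10.1 and Hoxc10 4.99% ± 4.61 (SD, n = 3), and Xist was at 83.8% to 120% of its Comma-D level on the 3 arrays. The 2 erbB2-positive fractions did not overlap, with a difference of -55.1 percentage points (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow, adjusted p = 0.111 over 10 comparisons). The 1:1 erbB2-negative and 1:50 erbB2-positive fractions overlapped when taken unpaired (exact p = 0.3, adjusted p = 0.3). If their replicate numbers pair them, as the correlations of residuals were taken to show, the 1:1 erbB2-negative array lay higher within 3 of 3 numbers. It did so by 3.905 to 19.13 percentage points (two-sided paired exact p = 0.25, the smallest that 3 pairs allow, adjusted p = 0.25 over 6 comparisons).

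**Figure D2:**
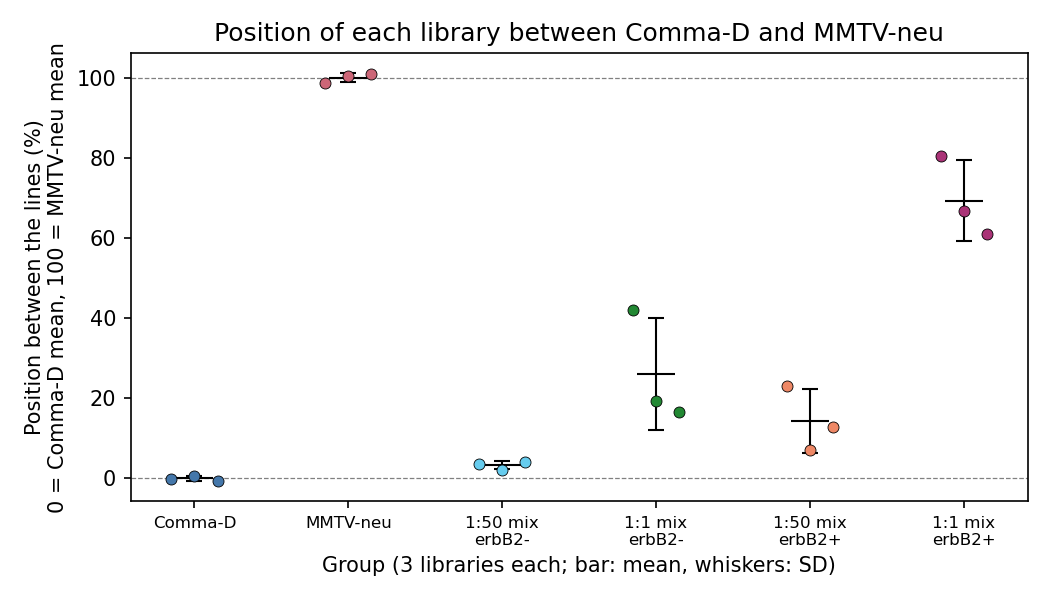
Position of each array between Comma-D (0%) and MMTV-neu (100%) in the 6 groups (points: arrays; bar and whiskers: mean and SD, n = 3). The 1:50 erbB2-positive arrays lie at 7.20% to 23.04% and the 1:1 erbB2-positive arrays at 61.0% to 80.5%. Of the 1641 genes behind the positions 1561 are lower in MMTV-neu.

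Some genes lay beyond both unmixed lines, where a blend of them would not be. In the 1:50 erbB2-positive fraction 36 genes were above and 111 below both, including Vsnl1 (2.14 log2 units above the nearer line), Snora20 (2.10) and Krt5 (1.37) above, and the water channel gene Aqp1 (1.18) and Dcn (0.712) below. Dcn lay at 5.063 in this fraction and 5.775 in MMTV-neu, both under the array medians, so its margin is weak evidence. In the 1:50 erbB2-negative fraction 65 were above and 52 below, among them Vsnl1 (2.21) and Krt5 (1.53) above, and Aqp1 (1.28) and Apol8 (1.13) below. The 1:1 erbB2-negative fraction had 26 above and 246 below, and the 1:1 erbB2-positive fraction 10 above and 164 below. Of these genes the 1:50 fractions shared 23 above and 46 below, but both were set against the same arrays of the lines and are paired by replicate number, so sharing is no separate evidence. The highest counts in 20 simulated sets of blends were 0 for the 1:50 and 8 for the 1:1 erbB2-negative fraction, and 1 and 11 for the erbB2-positive ones, beside 117, 272, 147 and 174 observed. The 117 became 50, 54, 54, 48 or 77 without Comma-D replicate 1, 2 or 3 or replicate 2 or 3 of the fraction, and 75 with centring. The 147 became 80, 90, 73 or 81 without Comma-D replicate 1, 2 or 3 or replicate 3 of the fraction, and 86 with centring. The 272 became 181, 151 or 151 without Comma-D replicate 1 or 3 or replicate 2 of the fraction. The 174 became 64 or 68 without replicate 2 or 3 of the fraction and 311 with centring.

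**Figure D3:**
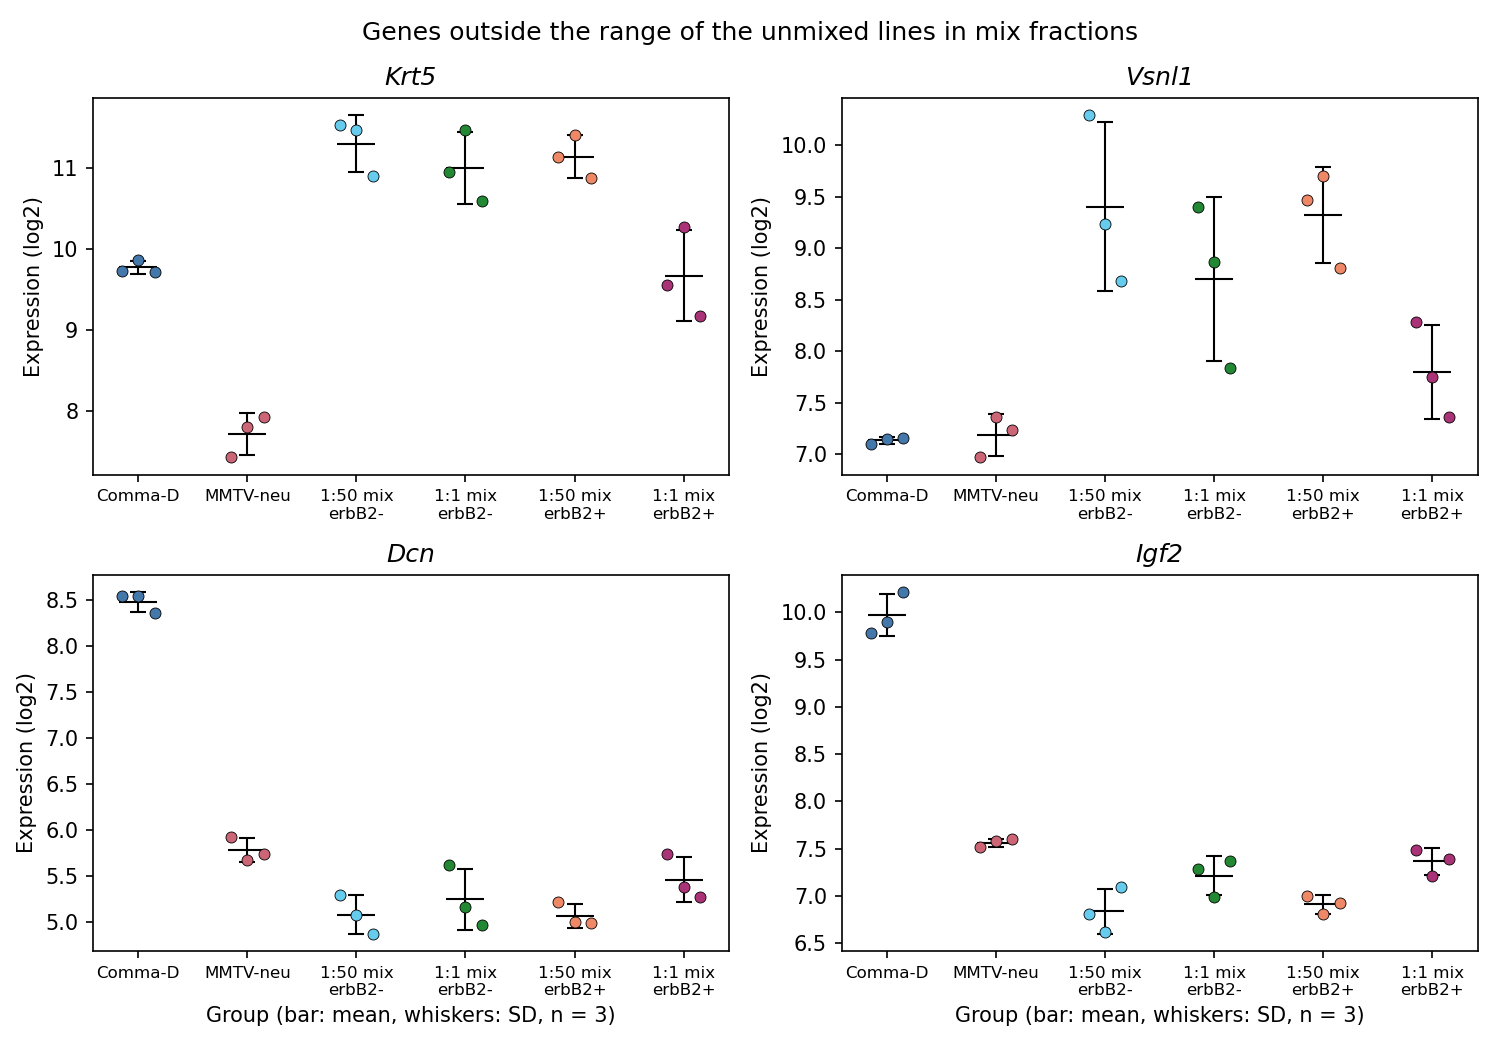
Log2 expression of Krt5, Vsnl1, Dcn and Igf2 on each array of the 6 groups, with axes that do not start at 0 (points: arrays; bar and whiskers: mean and SD, n = 3). Vsnl1 lies at 7.13 and 7.19 in the lines and 9.40 and 9.32 in the 1:50 fractions, and Igf2 at 9.97 and 7.57 in the lines and 6.84 and 6.91 in those fractions.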

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

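The following results drew a closer look because the interaction test found the effect of the ratio to differ between the erbB2-positive and erbB2-negative fractions. It called 548 genes. Among named genes the interaction was 2.84 (SE 0.32) for Snora20, 2.15 (SE 0.18) for Snord82, 1.94 (SE 0.27) for Krt8, 1.95 (SE 0.33) for Arhgap42, 1.05 (SE 0.18) for Errfi1, 1.59 (SE 0.16) for Dusp1, 1.51 (SE 0.22) for Axl, 2.21 (SE 0.52) for Zfp971 and 1.63 (SE 0.35) for Xist. It was 1.52 (SE 0.32) for Itgb1, 1.72 (SE 0.37) for Tnc, 1.15 (SE 0.27) for Ldha and 1.19 (SE 0.26) for Asns, and negative for Jph1 (-0.84, SE 0.15), Siva1 (-0.82, SE 0.17) and Cldn7 (-0.79, SE 0.18). With centring on the reference genes only Snora20 and Snord82 stayed called. Snora20 lay under the array medians in the erbB2-negative fractions and the 1:1 erbB2-positive fraction, so the size of its interaction is not exact. A pure blend of the lines can also give an interaction other than 0, because levels add on the linear scale and differences were taken on the log2 scale.

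The splits of arrays into other groups were chosen before the data were examined. For MMTV-neu minus Comma-D, the 1:50 erbB2-positive fraction minus either line, the erbB2-positive fractions, the 1:50 and 1:1 erbB2-negative fractions minus Comma-D and the erbB2-negative fractions, only 1 of 10 splits, the real one, reached the count, and the highest other was 0. It was also 1 of 10 for the 1:1 erbB2-positive fraction minus MMTV-neu (3658, highest other 81) and within the 1:1 co-culture (11195, highest other 4398), and 2 of 10 within the 1:50 co-culture (2, highest other 3). With 10 splits a share under 0.05 is impossible. For the interaction 6 of 100 groupings of the 12 co-culture arrays, the real one included, reached 548. The highest of the random draws reached 14263, so chance was not excluded and the draws point to a structure of the samples. A draw can place the ratio or sorting effect in this contrast. Draws that kept the arrays of a replicate number together were added after the result was seen. With the real grouping again included, 7 of 100 reached 548 (highest other 13214), and with a replicate block 3 of 100 reached its 2480 (highest other 11442).

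That the fractions lay between the lines was weighed with tests written after the result was seen. If they were blends of unchanged lines, 90% or more of axis genes were to lie between the lines in each fraction. The lowest share was 60.5%, in the 1:50 erbB2-negative fraction, where simulated blends gave 65.2% to 69.5%, so the bound of 90% was wrong there. All 4 fractions lay below their simulated ranges (98.6% against 99.5% to 99.9% for the 1:1 erbB2-negative, 92.9% against 94.3% to 96.2% for the 1:50 and 97.4% against 99.9% to 100% for the 1:1 erbB2-positive fraction). The simulated noise left out the fractions' own spread and shifts shared by replicate number, so these ranges may be too narrow to exclude blends alone. By calls against Comma-D the 1:1 fractions lay close to blends. These gave 6622 to 6844 calls for the erbB2-negative (7121 observed) and 15572 to 15712 for the erbB2-positive fraction (15615 observed). The 1:50 erbB2-negative and erbB2-positive fractions had 334 and 1139 calls, beside 0 and 18 to 170 in blends. If the 1:50 erbB2-positive fraction were mostly MMTV-neu RNA with Xist off, Xist was to stay low, but it was at 83.8% or more of its Comma-D level on each array, which does not bear this out. That fraction lay at 14.3% of the way to MMTV-neu, and 2 genes were called between it and the 1:50 erbB2-negative fraction. So few calls do not show that the 1:50 fractions are alike, since the arrays of 29.1% of genes did not overlap between them, against 10% by chance. A single MMTV-neu share per array accounted for 62.8%, 16.2% and 35% of the squared difference of the 1:50 erbB2-positive arrays from Comma-D over axis genes. The rest, noise of single arrays included, is left open by such a share. Carry-over of Comma-D cells or RNA may explain part or all of this fraction's position, and genotyping the sorted cells or counting rat neu alleles could decide it.

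That genes lay beyond both lines was weighed against blends by a test chosen before the data were examined, and against handling stress by a test chosen after the result was seen. Blends gave at most 11 genes outside the range in any fraction and the smallest observed count was 117. The simulated noise was independent and came from the unmixed arrays, so the fractions' own spread and shifts shared by replicate number were left out. The gap speaks against carry-over alone only as far as that noise is right. If dissociation and bead sorting had placed genes beyond both lines, immediate early and heat shock genes were to be higher in the 1:50 erbB2-negative fraction than in Comma-D, but their median difference was -0.449, with array means of 9.07 to 9.28 against 9.67 to 9.73. The predicted rise was not seen. The list still moved, so a difference in handling or culture between these groups is not excluded. Whether unmixed Comma-D cells went through the same sorting was not tested, and a mock-sorted Comma-D sample could separate sorting from co-culture.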

How the results depend on the processing

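Most calls rest on 3 arrays a group, and leaving out an array leaves 2 in its group, within a fit of the others. Array signal carries a background, which compresses ratios, so a low level limits how large a fold change can be read, falls to levels near the background are lower bounds in size, and no gene can be called absent. The fit without MMTV-neu arrays and the replicate block in a fit of the 12 co-culture arrays were added after the data were seen, as was the paired test of axis positions, which like the unpaired one gave no p under 0.05 in any pair of fractions because 3 pairs cannot go below 0.25. Over the 265 pairs of gene and comparison, called or not, the outcome stayed the same in 224 with arrays centred on reference genes, 239 after quantile normalization, 255 with array weights, and in 1558 of 1686 fits without an array. Where a count moved, the cause was not tested unless stated.

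With the lowest 40% of genes left out, genes called were 9895 for MMTV-neu minus Comma-D (17310 in the main setting), 9102 for the 1:50 erbB2-positive fraction minus MMTV-neu (16621), 8666 for the 1:50 minus 1:1 erbB2-positive fraction (14240), 1127 for the 1:1 erbB2-positive fraction minus MMTV-neu (3658), 1 between the 1:50 fractions (2) and 7167 between the 1:1 fractions (11195), with fewer genes tested by construction. Lists called were 8 for the erbB2-positive fractions (14), 3 for the erbB2-negative fractions (8) and 5 within the 1:50 co-culture (12). Genes outside the range of the lines were 74 and 176 in the 1:50 and 1:1 erbB2-negative fractions and 76 in the 1:1 erbB2-positive fraction.

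With every probe set on its own, calls were 29192 for MMTV-neu minus Comma-D, 27908 for the 1:50 erbB2-positive fraction minus MMTV-neu, 22576 between the erbB2-positive fractions, 7255 for the 1:1 erbB2-positive fraction minus MMTV-neu and 27 within the 1:50 co-culture, since more probe sets than genes were tested.

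Asking for a difference of at least 1 log2 unit left 7507 for MMTV-neu minus Comma-D, 5031 and 197 for the 1:50 erbB2-positive fraction minus MMTV-neu and minus Comma-D, 3127 between the erbB2-positive fractions, 391 for the 1:1 erbB2-positive fraction minus MMTV-neu, 101 and 560 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, 230 between these and 1626 within the 1:1 co-culture. At least 1 log2 unit beyond the nearer line were 18, 3, 9 and 0 genes in the 1:50 and 1:1 erbB2-negative and the 1:50 and 1:1 erbB2-positive fractions. An adjusted p under 0.01 left 414 for the 1:50 erbB2-positive fraction minus Comma-D, 1158 for the 1:1 erbB2-positive fraction minus MMTV-neu, 144 and 2990 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, 1174 between these, 7049 within the 1:1 co-culture and 87 for the interaction.

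With array weights, calls were 8970 for the 1:50 erbB2-positive fraction minus Comma-D, 5926 for the 1:1 erbB2-positive fraction minus MMTV-neu, 2425 and 13989 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, 14356 between these, 7024 and 16899 within the 1:50 and 1:1 co-cultures and 13911 for the interaction. The estimate of the weights did not converge and gave replicate 2 of the 1:1 erbB2-negative fraction a weight of 420, so a single array nearly stands for its group and these counts are unreliable. Erbb2 within the 1:50 co-culture turned from -0.05 to 0.10.

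Centring on the reference genes, which adds the same amount to every gene of an array, gave 220 calls for the 1:50 erbB2-positive fraction minus Comma-D, 12864 for the 1:1 erbB2-positive fraction minus MMTV-neu, 128 for the 1:50 erbB2-negative fraction minus Comma-D and 2 for the interaction. It turned Erbb2 to 1.28 and Erbb3 to 0.31 for MMTV-neu minus Comma-D, and Erbb2 to -1.01 for the 1:50 erbB2-positive fraction minus MMTV-neu, -0.43 between the erbB2-positive fractions and 0.20 within the 1:50 co-culture. It called 16 lists between the erbB2-negative fractions (8), put the 1:50 erbB2-negative fraction at 2.02% of the axis (3.27%) and counted 75, 86 and 311 genes outside the range in the 1:50 erbB2-negative, 1:50 erbB2-positive and 1:1 erbB2-positive fractions. The amount added reflects the reference genes' own differences, a mean fall of 1.42 for MMTV-neu minus Comma-D. Quantile normalization gave 406 calls for the 1:50 erbB2-positive and 188 and 3108 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, 901 between the erbB2-negative fractions and 946 for the interaction. It turned Erbb2 to 0.52 for MMTV-neu minus Comma-D, -0.36 for the 1:50 erbB2-positive fraction minus MMTV-neu, -0.0542 between the erbB2-positive fractions and 0.11 within the 1:50 co-culture.

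A replicate block gave 1875 calls for the 1:50 erbB2-positive fraction minus Comma-D and 1288 for the interaction, and in the fit of the 12 co-culture arrays 9438 between the erbB2-negative fractions and 2480 for the interaction. Of the 265 pairs of gene and comparison, called or not, 261 had the same outcome with the replicate block and 4 became called, and it changed no list call.

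A fit of the compared arrays only, with few residual degrees of freedom, gave 2123 calls for the 1:50 erbB2-positive fraction minus Comma-D, 793 for the 1:1 erbB2-positive fraction minus MMTV-neu, 1045 and 4231 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, 2 between these, 0 and 6904 within the 1:50 and 1:1 co-cultures and 67 for the interaction. The median over axis genes put the 1:50 erbB2-negative fraction at 1.70%.

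With an estimated correlation, lists called went from 15 to 0 for MMTV-neu minus Comma-D, from 16 to 0 and 7 to 1 for the 1:50 erbB2-positive fraction minus MMTV-neu and minus Comma-D, from 14 to 0 between the erbB2-positive fractions, from 16 to 0 for the 1:1 erbB2-positive fraction minus MMTV-neu, from 9 to 4 and 8 to 0 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, from 8 to 0 between these, from 12 to 0 and 14 to 0 within the 1:50 and 1:1 co-cultures and from 10 to 0 for the interaction. Without the MMTV-neu arrays 6 lists were called within the 1:50 co-culture.

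Leaving out single arrays gave 441 to 1485 calls for the 1:50 erbB2-positive fraction minus Comma-D, 1362 to 4387 for the 1:1 erbB2-positive fraction minus MMTV-neu, 146 to 289 and 2885 to 9193 for the 1:50 and 1:1 erbB2-negative fractions minus Comma-D, 1065 to 8726 between these, 6737 to 13221 within the 1:1 co-culture and 115 to 5303 for the interaction. Genes outside the range were 48 to 117, 151 to 306, 73 to 169 and 64 to 195 in the 1:50 and 1:1 erbB2-negative and the 1:50 and 1:1 erbB2-positive fractions. Positions on the axis ranged over 2.84 to 3.80, 18 to 30.7, 9.97 to 17.9 and 63.8 to 73.6% in that order. For the 1:50 erbB2-positive fraction minus Comma-D, Erbb2 (0.02) ranged from -0.0434 to 0.08697 and Xist (0.06) from -0.0480 to 0.21, and for the 1:1 erbB2-positive fraction minus MMTV-neu Krt8 (-0.05) ranged from -0.11 to 0.011.

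With single arrays left out, the adjusted p within the 1:50 co-culture ranged from 6.34e-08 to 0.65 for the list Cell cycle and mitosis genes and from 4.55e-06 to 0.65 for the list DNA replication genes (0.0355 each in the main setting, lower in the erbB2-positive fraction). Without replicate 3 of the erbB2-negative fraction both turned upward (adjusted p = 0.159 and 0.417).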

Other observations

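All tests on the missing signal of MMTV-neu were written after the result was seen. If the arrays were merely dim, the order of genes was to be kept, but 40 of the 500 genes highest in Comma-D lay under the array median on all 3 MMTV-neu arrays, against 0 in each co-culture fraction. Uniform loss alone would not give this. Lines that differ in expression would also change the order, so the count does not exclude dim arrays beside such a difference. If RNA of another species, whose sequence differs more in fast-evolving genes, had met mouse probes, CD antigen genes were to fall by at least 1 log2 unit more than splicing, translation and proteasome genes. The 12 CD antigen genes had a median of -3.67 and the 79 others -1.23, a further fall of 2.45 (two-sided permutation of genes between the classes, p = 1e-05, the smallest that 100000 resamples allow). Genes are not independent replicates, so this p does not measure how likely RNA of another species is. RNA of another species would give such a fall, but a difference between the lines or their media could give it too. Hairpins classed by their miRNA numbers alone as shared by vertebrates (159) exceeded those classed as rodent-restricted (29) by 0.231 (permutation p = 0.089). Both classes had Comma-D medians under the array medians, at 5.01 and 5.02, where background compresses ratios. These causes cannot be told apart by this test, and sequencing the MMTV-neu RNA might settle it. Degraded RNA, which could also lower Actb and other abundant transcripts, was not tested, since a single value per probe set shows no profile along a transcript.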
